A study of Caenorhabditis elegans with 16 samples.

How the data were processed

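PolyA RNA of whole worms was sequenced in 16 libraries, 4 of each combination of strain (N2 or hlh-30(tm1978)) and diet (ad libitum, AL, or starvation for 24 hours, ARD), with worms grown at 20 °C on E. coli OP50, per the labels' protocols. The starved worms were taken as larvae at the mid L3, washed free of bacteria and kept on agarose with ampicillin, per the labels. Libraries were made with a directional kit, per the labels. The submitters' processing notes name HISAT 0.1.6, StringTie 1.0.4 and Cuffdiff 2.2.1 with the genome build WBcel235. Read filtering, the annotation used, the strand setting and the normalization option were not given in the sources used here.

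The data analysed were the authors' deposited Cuffdiff comparison table of 278274 lines, with 46192 gene IDs in 6 pairwise comparisons of the groups. It gives 1 group value per gene and no value per library, so columns per library numbered 0. The group values are FPKM by the layout of the Cuffdiff output the authors deposited, while the header names no unit, so the unit rests on that layout. The log2 fold change between the 2 group values was deposited as the authors computed it, with a test statistic. The p-value and the q-value were also deposited by the authors, and the q-value matched a Benjamini-Hochberg adjustment over the 99671 tests of all 6 comparisons together, to within a relative difference of 4.83e-06. The smallest p was 5e-05 and the smallest q 0.000246, so the order among the strongest calls cannot be read from them. The group named h30 in the header was read as the hlh-30 strain. Because the files give no counts, depth was unknown, and no interval for counting error is given.

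The tests fixed before the data were examined, a count model or limma over all libraries with camera for gene lists, need values per library and could not be run. As the same design foresaw for a table of group values, the authors' q under 0.05 was taken as their call and no test was run here for the 4 comparisons of N2 ARD with N2 AL, hlh-30 ARD with hlh-30 AL, hlh-30 AL with N2 AL and hlh-30 ARD with N2 ARD. The labels do not say whether the 4 replicates of a group were separate cultures, and the p-values measure only the spread between these samples. Lines with the same gene and locus were joined into 1 feature, 17497 were tested in at least 1 of the 4 comparisons, and 225 of them merge more than 1 gene. Of the gene IDs 93.4% were in the reference name table, and 96.9% of single-gene tested features were in the Ensembl release 115 annotation of WBcel235, 100% of these on the same chromosome and 99.99% overlapping the deposited coordinates, which supplied the positions and exon lengths.

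Whether the starvation response differs between strains was tested in a way chosen after the data were seen. The mutant's log2 fold change minus that of N2 was divided by the root of the summed squared standard errors, each taken as the fold change divided by the deposited statistic and by 2. Squared ratios of fold to statistic added up over the groups to within a relative departure of 1.93e-05 for 14269 features. The factor 2 brings the statistic near the deposited p at the median, the ratio of implied to deposited statistic being 1.95, 1.96, 2.09 and 2.01 in the 4 comparisons. The implied statistic was read from a normal distribution. Single features departed from 2, with percentiles 5 and 95 of the ratio at 0.80 and 3.31 for starvation in N2 and 0.78 and 3.45 in the mutant. The standard errors are therefore approximate. The two-sided p used a t reference with 12 residual degrees of freedom, with Benjamini-Hochberg adjustment over 16164 features. The test was checked on simulated data for these 16164 features with 50 planted differences of each size. A normal reference, tried first, called 77 unchanged and 92 changed features and was replaced, while the t reference called 2 unchanged and 45 changed ones. The simulated spread was given the error of 12 degrees of freedom, which builds in an advantage of the t reference. The deposited statistics need not have that error. At log2 differences of 1, 2, 3 and 4 the t reference found 0, 1, 13 and 31 of 50.

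Gene lists, 46 in number and 45 of them described as sets, were written from general knowledge before the data were examined, and a list was used where at least 5 members were tested. Members past the threshold were counted over all features and adjusted over the list alone, and the list median was set against 10000 random lists of the same size matched on mean FPKM. On simulated data for 16848 features of the comparison of starved strains this placed 1 of 40 unshifted and 37 of 40 shifted lists outside the central 95% of random lists. The simulated genes were independent, so this cannot show how often a list of genes that vary together would fall outside. The percentiles are therefore used as descriptions and not as p-values. The match drew from bins of features ranked by mean FPKM, and list members stayed in the pool. The bin of the most abundant features spans a wide range, so lists such as ribosomal proteins were set against many less abundant genes. Annotation terms of 10 to 500 members were tested with a one-sided hypergeometric test, per direction, against the tested features that carry a term, with Benjamini-Hochberg adjustment. That test treats genes as independent and is not matched on level, so its q can overstate the evidence. Correlations and overlaps were computed across features, between comparisons that share no library.

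Genes named in the text follow a rule written before the data were examined. It takes hlh-30 in every group, then per comparison the 8 rising and 8 falling named genes of largest log2 fold change past the threshold with a mean of at least 5 FPKM in the higher group, then up to 4 members of each list described, by absolute fold, and finally a fixed set of key genes. The rule also asked that the libraries of the groups not overlap and, for the difference of responses, that the sign hold in every leave-one-out, and neither condition could be applied to group values. Genes outside the rule are said to be chosen after their values were seen.

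Alternatives were a q of 0.01, a 2-fold minimum, a minimum of 1 FPKM, leaving out merged features, adjustment within each comparison, standard errors from the deposited statistic, 3 rescalings of the fold changes, and for the difference of responses another reference distribution and other standard errors. All except the q and 2-fold thresholds and the lack of a filter for the correlations were chosen after seeing the data. Results were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Group values of exactly 0 give no fold change here and are called listed at 0. The 2 comparisons that cross both strain and diet were not used here.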

Results

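The data covered polyA RNA from whole Caenorhabditis elegans of the N2 wild type and of hlh-30(tm1978), a deletion mutant of the gene for the worm's TFEB-like transcription factor, which in fed and starved animals acts on genes of lysosomes, autophagy and fat use. Each strain was sampled with food present without limit (AL, labelled mid L3) and 24 hours after removal from food at the mid L3 (ARD, adult reproductive diapause, a quiescent state of starved worms), with 4 libraries in each of 4 groups and 16 in all. Values were the authors' deposited table of group values, read as FPKM, with the log2 fold change and q of each comparison. That table gives 1 value per group, so no SD of the libraries is printed and read depth was unknown. The sum of FPKM over features was 1.72e+06 in N2 AL, 1.35e+06 in N2 ARD, 1.45e+06 in hlh-30 AL and 794646 in hlh-30 ARD, and 11999, 14331, 11912 and 14832 features reached 1 FPKM in these groups. A feature is a gene or a merged locus of the table, "higher", "lower", "rose" and "fell" are used of features past q = 0.05, and 0.000246 was the smallest q in the table.

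Because the groups differed in these sums, every direction was also read after 3 rescalings, 2 of which subtract the median log2 fold change of all tested features or of features with a mean of at least 5 FPKM, while the last scales the groups to equal sums. For starvation in N2 those shifts were 0.44, -0.61 and -0.35, and for starvation in the mutant 0.55, -0.68 and -0.87. For mutant against N2 they were -0.04, -0.04 and -0.25 in fed worms and 0.17, 0.04 and -0.76 in starved worms. They are called the all-feature centring, the 5 FPKM centring and the equal-sum scaling, and folds are otherwise as deposited.

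The targeted gene, hlh-30 (WBGene00020930, WBcel235 chromosome IV, 4014793 to 4034951, minus strand), was lower in both mutant groups, whose strain label names the allele tm1978. The authors' deposited table gave hlh-30 25 FPKM in N2 AL, 80.4 in N2 ARD, 6.63 in hlh-30 AL and 21.7 in hlh-30 ARD, with a log2 fold change of mutant against N2 of -1.92 in fed and -1.89 in starved worms (q 0.000246 for each). The deposited feature runs from 4014799 to 4028127, which is not the whole gene. Its value is not limited to the deleted part, so it checks the deletion only in part. The RNA was higher in starved than in fed worms of both strains, by 1.69 in N2 and 1.71 in the mutant in the authors' deposited table, and the difference between the responses was 0.02 (SE 0.472, q 1.0).

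The comparison of starved with fed wild-type worms, the baseline for any role of hlh-30, gave lower transcripts of egg production and growth and higher ones of lipases, DAF-16-induced genes and cuticle formation. The fed libraries, labelled mid L3, held yolk protein transcripts made by adults, so a difference of stage is not excluded from this comparison or from the same one in the mutant. Yolk protein, oocyte, germline and cell cycle genes fell, together with the proteasome and ribosome biogenesis. Most lipase, DAF-16-induced, moulting, collagen and neuropeptide genes rose, as did 7 of 16 small and inducible heat shock proteins. Of 16812 tested features 9136 passed, 4622 higher and 4514 lower in starved N2, and 4555 and 4361 of them changed at least 2-fold. With the all-feature centring 4466 of 10326 calls were higher, with the 5 FPKM centring 7196 of 10412 and with the equal-sum scaling 6602 of 10602.

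**Figure D1:**
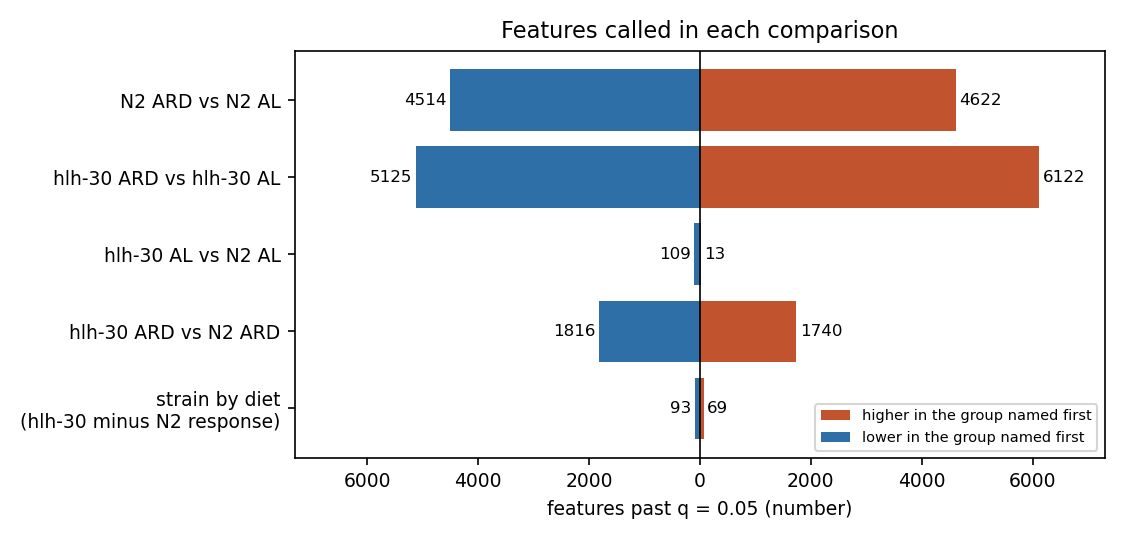
Number of features past q = 0.05 in each comparison, with bars to the right for features higher in the group named first and bars to the left for lower ones. Starvation gave 4622 higher and 4514 lower in N2, and mutation gave 13 and 109 in fed against 1740 and 1816 in starved worms; with the equal-sum scaling the starved split became 6694 higher of 7383.

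All 7 tested lipl genes, which encode lysosomal and related lipases that free fatty acids from stored fat, rose in starved N2, with a median log2 fold change of 3.92 (7 of 7 adjusted over the list alone). The authors' deposited table listed lipl-3 at 0.492 FPKM in fed and 125 FPKM in starved N2, a log2 fold change of 7.99 (q 0.000246), and gave 5.36 for lipl-2, 4.93 for lipl-1, 3.92 for lipl-6 and 1.74 for lipl-4. Enzymes that burn the freed fatty acids went with them in part. In the authors' deposited table acs-2, a mitochondrial acyl-CoA synthetase of the fasting response, rose from 17.2 to 1009 FPKM (5.87) and cpt-3, a carnitine palmitoyltransferase, rose by 3.89. The wider list of fasting-induced fatty acid use was split, with 8 of 34 higher and 11 lower (8 and 12 adjusted over the list alone), a mean of 0.32 against a median of -0.34, and a median of 0.27 under the 5 FPKM centring and 0.01 under the equal-sum scaling. Among enzymes of fatty acid synthesis and desaturation 11 of 24 rose and 4 fell (12 and 5 adjusted over the list alone). The authors' deposited table gave the elongases elo-7 and elo-4 3.58 and 3.17 and the desaturase fat-3 3.09. The stearoyl-CoA desaturases moved apart in the authors' deposited table, fat-5 and fat-6 rising by 1.39 and 1.84 while fat-7 fell by 3.86, although fat-6 and fat-7 are close copies whose reads can be misassigned. The gene of the glyoxylate enzyme isocitrate lyase and malate synthase, icl-1, which lets worms make sugar from fat, rose from 73.3 to 1163 FPKM in the authors' deposited table. Its list had 4 of 9 genes higher and 3 lower (median 0.49).

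Of 24 tested genes known to be induced by the FOXO factor DAF-16, 19 rose and 1 fell (19 and 2 adjusted over the list alone, median 2.80). Small and inducible heat shock proteins had 7 of 16 higher and 1 lower (median 2.35). Other stress lists did not rise as a whole. The unfolded protein response had 2 of 21 higher and 14 lower (median -1.14), and antioxidant enzymes 5 of 22 higher and 7 lower, with a median of -0.25 that became 0.37 under the 5 FPKM centring and 0.10 under the equal-sum scaling. Most abundant in starved N2 among the DAF-16-induced genes was tts-1, a long noncoding RNA that binds ribosomes in long-lived worms, which rose from 156 to 32620.5 FPKM in the authors' deposited table, a log2 fold change of 7.70 (q 0.000246). The authors' deposited table also gave sodh-1, an alcohol dehydrogenase, 7.14, the metallothionein mtl-1 7.05, the chaperones hsp-12.6 and hsp-12.3 4.95 and 4.66, and the superoxide dismutase sod-3 2.41. The flavin monooxygenase gene fmo-2, of the fatty acid use list, had 7.14 there. Large rises outside these lists in the authors' deposited table included the fatty acid and retinol binding gene far-7 (7.38), the P450 gene cyp-37B1 (8.55) and the lectin gene clec-61 (9.45, q 0.0167). Of the autophagy genes 4 of 26 rose and 4 fell, with a median of -0.20 that became 0.41 under the 5 FPKM centring and 0.15 under the equal-sum scaling. The authors' deposited table gave the ubiquitin-like lgg-1 and the receptor sqst-1 1.58 and 1.96. Lysosomal acid hydrolases were also split, 9 of 37 higher and 14 lower (10 and 15 adjusted over the list alone), with a median of -0.32 that became 0.30 and 0.04 under the same 2 scalings.

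Moulting genes, which build and shed the cuticle, had 21 of 25 higher and 1 lower (23 and 1 adjusted over the list alone, median 3.14). Cuticle collagens had 85 of 154 higher and 6 lower (92 and 7 adjusted over the list alone, median 3.45). The authors' deposited table gave the protease inhibitor gene mlt-11 6.36, the patched-related ptr-4 6.11, the collagens rol-6 6.41 and col-172 6.35, and the period-like timing gene lin-42 2.86. Of the neuropeptides 56 of 75 were higher and 1 lower (median 2.18), and of the insulin-like peptides 19 of 35 were higher and 0 lower (median 1.87). Markers of some tissues rose with them. Pan-neuronal genes had 9 of 21 higher and 1 lower (median 1.32). Pharynx had 11 of 15 higher and 0 lower (median 1.86) and epidermis 9 of 19 and 2 (median 0.88). Fewer were higher in body wall muscle, 3 of 25 with 2 lower (median 0.36). Vulva, uterus and somatic gonad had 4 of 21 higher and 3 lower (median 0.61) and intestine 7 of 21 and 4 (median 0.35). Against random lists matched on level, these medians lay in order at percentiles 86.885, 91.135, 69.985, 97.79, 15.03 and 88.31. The pan-neuronal, pharynx and epidermis medians were thus within the range of other genes. The libraries came from whole worms, so a smaller share of germline in starved worms is not excluded as a source of the rises of neuropeptide, tissue marker and cuticle genes. Of 195 nuclear hormone receptors 102 were higher and 8 lower (108 and 8 adjusted over the list alone, median 1.32), but that median lay at percentile 58.2 of random lists of genes of like level, so they rose no more than such genes. In the authors' deposited table the insulin-like ins-11 and ins-35 rose by 7.16 (q 0.0129) and 5.14, and the cytochrome P450 gene of dafachronic acid synthesis daf-9 by 2.08, while the insulin receptor gene daf-2 and the FOXO gene daf-16 did not pass. Among annotation terms, structural constituent of cuticle held 86 higher features of 151 where 36.5 would fall by chance (q 2.76e-15). The term test is not matched on level. It gave steroid hormone receptor activity a q of 2.36e-14, although the nuclear hormone receptors rose no more than genes of like level.

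Reproduction and growth went down, and the medians of the oocyte, germline, cell cycle, vitellogenin, proteasome and ribosome biogenesis lists were negative under every rescaling. All but 1 of 19 oocyte genes fell (median -3.53, 19 adjusted over the list alone) and 42 of 45 genes of the mitotic and meiotic germline fell (median -2.41, 43 adjusted over the list alone). Likewise 38 of 41 cell cycle and replication genes fell and 1 rose (median -2.60). Of 6 vitellogenins, the yolk protein genes of the adult intestine, 5 fell (median -6.44). In the authors' deposited table vit-5 dropped from 1857 to 135 FPKM while vit-2, at 3538 and 2123 FPKM, did not pass (q 0.331). Reads of vit-3 and vit-4 are hard to tell apart, and the authors' deposited table gave them -9.56 and -9.11. The authors' deposited table gave the yolk receptor rme-2 -4.19, the eggshell gene cbd-1 -4.28, the maturation regulator oma-1 -3.53, the germline RNA helicase cgh-1 -3.72, the replication helicase mcm-7 -3.55 and the cyclin cyb-3 -3.45. Proteasome subunits had 31 of 32 lower (median -1.99) and ribosome biogenesis 25 of 29 (median -1.75; 26 lower and 1 higher adjusted over the list alone), with fibrillarin (fib-1) at -2.72 in the authors' deposited table. Ribosomal protein genes did not follow, with 2 of 75 higher and 2 lower and a median of -0.30 that became 0.32 under the 5 FPKM centring and 0.06 under the equal-sum scaling. Sperm genes moved against the other germline lists, 37 of 77 higher and 3 lower (median 1.54), although the major sperm protein genes are near-identical copies.

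The response of hlh-30 mutants to starvation asks how much of that program is kept when the factor is missing. Yolk, oocyte, germline and cell cycle genes fell and moulting, collagen and neuropeptide genes rose, as in N2. Most ribosomal protein, oxidative phosphorylation and TCA cycle genes fell as well, but no further than other genes of the same wide bins of level. Their medians lay at percentiles 49.5, 54.7 and 49.7 of random lists matched on level. Of 17084 tested features 11247 passed, 6122 higher and 5125 lower, with 5910 and 4644 changed at least 2-fold. The split became 5508 higher of 12033 with the all-feature centring, 8308 of 11777 with the 5 FPKM centring and 8695 of 11575 with the equal-sum scaling.

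In the mutant 5 of 7 lipases rose (median 2.22), and the authors' deposited table gave lipl-1 5.30 and lipl-6 4.74 but lipl-3 2.2 (q 0.0135), from 0.0919 to 0.421 FPKM. DAF-16-induced genes had 13 of 24 higher and 3 lower (median 1.41). The authors' deposited table gave mtl-1 9.41, sodh-1 6.67 and sod-3 2.26, while hsp-12.6 did not pass (-0.08). Small and inducible heat shock proteins had 2 of 12 higher and 1 lower (1 and 1 adjusted over the list alone), with a median of 0.11 that became -0.44 under the all-feature centring. Fatty acid synthesis and desaturation had 4 of 24 higher and 10 lower (6 and 11 adjusted over the list alone), with a median of -0.67 that became 0.01 under the 5 FPKM centring and 0.20 under the equal-sum scaling. The authors' deposited table gave fat-5 -4.44 (q 0.0123), fat-6 -2.63 and fat-7 -7.18 against 4.74 for elo-7. The authors' deposited table gave acs-2 2.41, while icl-1 did not pass (0.05, q 0.917), and acdh-1, a short-chain acyl-CoA dehydrogenase, fell by 3.32.

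The cuticle program was large in the mutant, with 24 of 25 moulting genes higher and 1 lower (median 4.09) and 96 of 148 collagens higher and 6 lower (97 and 6 adjusted over the list alone, median 3.93). The authors' deposited table gave mlt-11 8.60, the hedgehog-like qua-1 7.94, the collagens dpy-7 7.90 and rol-6 7.37, and wrt-8 8.53 (q 0.000659). The authors' deposited table gave the peptides nlp-34 7.09, nlp-30 5.13 and nlp-25 4.88. Neuropeptides had 61 of 75 higher and 0 lower (median 2.43). Markers of several tissues again rose with them, pan-neuronal genes 14 of 21 with 1 lower (median 1.92), pharynx 11 of 15 with 0 lower (median 2.43) and epidermis 14 of 18 with 0 lower (median 1.53). Vulva, uterus and somatic gonad had 11 of 21 higher and 4 lower (median 1.33). Body wall muscle had 9 of 25 higher and 4 lower (median 0.27, -0.28 under the all-feature centring). The intestine was split, with 7 of 21 higher and 8 lower (median -0.29). A change in the share of tissues is not excluded here either. The TGF-beta ligand daf-7 and the insulin-like daf-28, both made by food-sensing neurons, rose by 3.26 and 2.06 (q 0.00221) in the authors' deposited table.

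On the falling side were all 6 vitellogenins (median -7.55), 18 of 19 oocyte genes (median -4.2, 19 adjusted over the list alone), 40 of 45 germline genes (median -1.68, 41 adjusted over the list alone) and 40 of 41 cell cycle genes with 1 higher (median -2.49). Sperm genes did not fall with them, 31 of 76 being higher and 3 lower (32 and 3 adjusted over the list alone, median 0.60), where 6122 of all 17084 tested features were higher. Their median lay at percentile 94.6 of random lists matched on level, and the all-feature centring subtracts 0.55 from it. In the authors' deposited table vit-2 fell from 3670.2 to 355 FPKM (q 0.00205), and the log2 fold change was -5.12 for oma-2, -4.85 for rme-2 and -4.25 for cyb-3. Proteasome subunits had 31 of 32 lower (median -2.26), ribosome biogenesis 23 of 29 (median -1.41, 24 adjusted over the list alone), and cytosolic ribosomal proteins 63 of 75 lower and 1 higher (median -1.3, 65 and 1 adjusted over the list alone). With the equal-sum scaling the ribosomal median was -0.43, with 4 higher and 4 lower. Oxidative phosphorylation had 24 of 27 lower (median -1.28), the TCA cycle 13 of 18 lower and 1 higher (median -1.29; 15 and 1 adjusted over the list alone) and glycolysis 14 of 18 lower and 1 higher (median -1.48), and with the equal-sum scaling 6, 5 and 9 of these were lower and 1, 2 and 2 higher. Lysosomal hydrolases had 20 of 35 lower and 7 higher (median -1.09; 21 and 7 adjusted over the list alone), the cathepsin gene cpl-1 falling from 1596 to 117 FPKM in the authors' deposited table. Autophagy had 14 of 26 lower and 2 higher (median -0.97), against 3 lower and 6 higher with the equal-sum scaling (median -0.11). Against random lists matched on level the medians of glycolysis, hydrolases, autophagy and ribosome biogenesis lay at percentiles 18.4, 30.6, 21.6 and 11.6, so these falls too were within the range of other genes.

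Across the genome the responses of the strains ran together. Over 16164 features the log2 fold changes correlated with a Pearson r of 0.901 and a Spearman rho of 0.911, and 91.3% had the same sign. Genes are not independent replicates, so no p is given. Higher in both were 3850 features where independent lists would share 1625, and lower in both 4044 against 1404, while 46 and 18 moved in opposite directions. The comparisons have no library in common.

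In fed worms the loss of hlh-30 was followed by a short list of changed genes, most of them lower, and none of the reproductive and cell cycle genes listed passed. Among the most reduced were tts-1, the alcohol dehydrogenase gene sodh-1 and the DAF-16 target dod-3. Lysosomal proteases cpr-1 and cpr-4, the transcription factor gene mdl-1 and antibacterial lysozymes were also lower. Of 14726 tested features 122 passed, 13 higher and 109 lower in the mutant, with 12 and 93 changed at least 2-fold. The count moved with the processing: adjusted within the comparison it was 23, all lower, and of the calls made after rescaling 13 of 56 were higher with either centring and 16 of 42 with the equal-sum scaling.

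The authors' deposited table gave tts-1 156 and 11.1 FPKM in fed N2 and mutant (log2 fold change -3.82), and gave -2.85 for sodh-1, -2.24 for dod-3 and -2.29 (q 0.0158) for the thaumatin gene thn-1. The DAF-16-induced list had 6 of 23 lower and 0 higher (5 lower adjusted over the list alone, median -0.73). The MAD-like mdl-1, a basic helix-loop-helix repressor, was at -1.76 in the authors' deposited table, and the other gene called in its list of longevity and starvation factors was hlh-30 itself. For the lysosome, in the authors' deposited table cpr-1 and cpr-4, cathepsin B-like proteases, had log2 fold changes of -1.71 and -1.5 (q 0.000659), the only calls among 35 hydrolases (median -0.28). The authors' deposited table gave lipl-3 -2.42 (q 0.00853) from 0.492 to 0.0919 FPKM, the only call among 5 lipases. None of 26 autophagy genes passed, and their median of -0.04 became 0.20 with the equal-sum scaling. Lysozymes and saposin-like antimicrobial genes had 4 of 32 lower (0 adjusted over the list alone, median -0.59), with lys-5 at -1.48 (q 0.0159) and spp-2 at -1.24 (q 0.00532) in the authors' deposited table. The term defense response to Gram-positive bacterium held 4 lower features of 32 against 0.163 by chance (q 0.0119). In fat use 3 of 32 were lower and 1 higher (1 and 0 adjusted over the list alone, median -0.15, which the equal-sum scaling made positive), namely acs-2 at -1.3 (q 0.00300), fmo-2 at -1.70 and hacd-1 at -0.78 against 1.14 for the enoyl-CoA hydratase gene ech-9 in the authors' deposited table. The glyoxylate gene icl-1 had -0.95 in the authors' deposited table (q 0.0156, 0 adjusted over the list alone). The few higher genes in the authors' deposited table included the fungus-induced fip-6 (1.62, q 0.0431) and the P-type ATPase gene catp-3 (1.02, q 0.0193). No higher gene passed when the adjustment was made within the comparison. Of the vitellogenins, oocyte, germline, cell cycle and ribosomal protein genes 0 passed, with 225 of all tested features at an unadjusted p under 0.05. The ribosomal protein genes still had a median of -0.39 (interquartile range -0.42 to -0.33), at percentile 0.065 of random lists matched on level. The medians of the vitellogenin, oocyte, germline and cell cycle lists were 0.06, -0.09, 0.06 and -0.03.

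In starved worms, the comparison closest to the series title, mutants had lower transcripts of many genes of fat metabolism, respiration and the DAF-16-induced list. Most genes tested of fatty acid synthesis and desaturation, the lipl lipases, the glyoxylate cycle, respiration, ribosomal proteins and the targets of DAF-16 were lower. On the other side 13 of 25 moulting genes were higher, with 8 of 19 epidermis, 62 of 189 innate immune response and 9 of 45 germline genes. Moulting, epidermis and germline genes thus differed in part between the starved strains. A difference of stage or of tissue shares between them is therefore not excluded from this comparison. Of 17121 tested features 3556 passed, 1740 higher and 1816 lower in the mutant, with 1554 and 1613 changed at least 2-fold. The split became 1121 higher of 3117 with the all-feature centring and 6694 higher of 7383 with the equal-sum scaling.

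Fat genes gave large falls. The desaturase fat-5 (WBGene00001397, chromosome V, 17725004 to 17726818) was at 78.2 FPKM in starved N2 and 0.830 in the starved mutant in the authors' deposited table, a log2 fold change of -6.56 (q 0.00504). The authors' deposited table gave fat-6 1380.2 and 42.6 FPKM in those groups (-5.02), and the log2 fold change of fat-7 was -4.03 and the triglyceride synthesis gene dgat-2 was -4.29. Of 24 genes of the list 13 were lower and 1 higher (14 and 1 adjusted over the list alone, median -1.54), and 12 lower and 6 higher with the equal-sum scaling (median -0.77). The nuclear receptor gene nhr-80, which activates these desaturases, had -2.0 in the authors' deposited table, while its relative nhr-49 did not pass (-0.63). Lipases had 4 of 7 lower and 0 higher (median -2.17), and 4 and 3 with the equal-sum scaling (median -1.41). The authors' deposited table gave lipl-3 -8.21, lipl-2 -3.12, lipl-4 -2.89 and lipl-5 -2.17, while lipl-1 did not pass (0.38, q 0.530). In the authors' deposited table acs-2 was at 1009 FPKM in N2 and 37.3 in the mutant (-4.76), the hydroxyacyl-CoA dehydrogenase gene hacd-1 at 835 and 23.5 (-5.15), and icl-1 at 1163 and 39.4 (-4.88). The gluconeogenic pck-2 had -2.93 in the authors' deposited table. In its list 8 of 9 genes of the glyoxylate and gluconeogenesis list were lower (median -1.14), and 2 with the equal-sum scaling (median -0.38). Of 34 genes of fatty acid use 15 were lower and 3 higher (16 and 3 adjusted over the list alone, median -0.83; 7 and 7 with the equal-sum scaling).

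**Figure D2:**
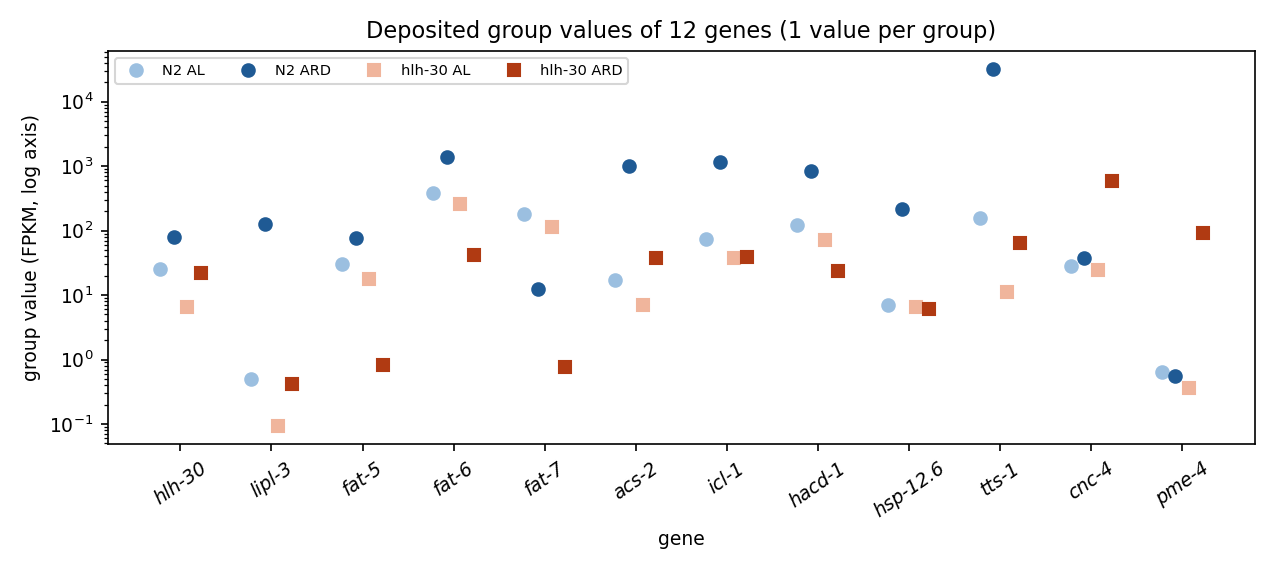
FPKM of 12 genes in the authors' deposited table on a log axis, 1 value per group, with circles for N2 and squares for hlh-30, pale for AL and dark for ARD. The starved mutant lies far below starved N2 for lipl-3 (0.421 against 125), fat-6 (42.6 against 1380.2) and tts-1 (63.3 against 32620.5), and above it for cnc-4 (588 against 37.9) and pme-4 (90.6 against 0.555).

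DAF-16-induced genes had 17 of 24 lower and 1 higher (19 and 2 adjusted over the list alone, median -2.06), and small and inducible heat shock proteins 7 of 16 lower and 0 higher (median -1.41). With the equal-sum scaling the DAF-16-induced list had 12 lower and 4 higher (median -1.3) and the heat shock list 6 lower and 0 higher (median -0.64). Some members are in both lists and fat-5 is also in the desaturation list. The noncoding RNA tts-1 (chromosome X, 1504131 to 1504841) was at 32620.5 FPKM in starved N2 and 63.3 in the mutant in the authors' deposited table (-9.01, q 0.000246). The authors' deposited table further gave hsp-12.6 -5.16, hsp-12.3 -3.72, dod-3 -5.71 and hsp-16.41 -4.14, although hsp-16 genes occur as near-identical pairs. It also gave -3.21 for fmo-2, which is in the list of fatty acid use and in neither of these 2 lists. Against the DAF-16-induced list, the metallothionein mtl-1 was higher (1.47, q 0.000460) and sod-3 did not pass (-0.80, q 0.0815) in the authors' deposited table. Of the transcription factors 10 of 22 were lower (median -0.60, which became 0.17 with the equal-sum scaling), with mdl-1 at -5.15 and mxl-3, a repressor of lysosomal lipases in fed worms, at -4.05 in the authors' deposited table. The AMP-activated kinase gene aak-2, an energy sensor, had -1.54 in the authors' deposited table, while daf-16 and daf-2 did not pass.

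For the lysosome, 20 of 36 acid hydrolases were lower and 3 higher (21 and 3 adjusted over the list alone, median -0.97), and 12 and 8 with the equal-sum scaling (median -0.21). The authors' deposited table gave cpl-1 -3.17, asp-1 -2.85, cpr-1 -3.47 and the membrane protein gene lmp-1 -2.62. Autophagy had 10 of 26 lower and 0 higher (8 adjusted over the list alone), with a median of -0.76, but with the equal-sum scaling the median was -0.00 and 5 were higher against 2 lower. A scaling moves all genes alike, and against random lists matched on level the autophagy median and the hydrolase median both lay at percentile 0.0. The authors' deposited table gave epg-9 -2.36, lgg-2 -1.87, atg-18 -1.46, unc-51 -1.39 and lgg-1 -0.97 (q 0.0103), while sqst-1 did not pass (0.57, q 0.180). The proton pump that acidifies lysosomes had 1 of 18 subunits higher and 0 lower (0 adjusted over the list alone, median -0.10, 0.66 with the equal-sum scaling).

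Among energy and translation genes the counts of lower genes depended on the scaling. Cytosolic ribosomal proteins had 63 of 75 lower and 0 higher (65 adjusted over the list alone, median -1.38), a median of -0.62 and 8 lower with the equal-sum scaling. The authors' deposited table gave rps-26 4883 FPKM in N2 and 1506 in the mutant (-1.70) and rpl-25.1 a log2 fold change of -1.96. Oxidative phosphorylation had 18 of 27 lower (median -1.27), and 9 lower and 1 higher with the equal-sum scaling (median -0.51). The TCA cycle had 9 of 18 lower (median -0.82, 11 adjusted over the list alone), but 0 lower and 2 higher with the equal-sum scaling (median -0.05). Glycolysis had 9 of 18 lower and 1 higher (median -0.80; 10 and 1 adjusted over the list alone), and 2 lower and 3 higher with the equal-sum scaling (median -0.03). The authors' deposited table gave the ATP synthase gene atp-3 -1.72, aconitase aco-2 -1.57 and aldolase aldo-2 -2.89. One-carbon and methionine genes had 12 of 18 lower and 1 higher (median -1.2), and 4 and 2 with the equal-sum scaling (median -0.43). Against random lists matched on level, the medians of ribosomal proteins, oxidative phosphorylation, the TCA cycle, glycolysis and one-carbon genes lay at percentiles 0.0, 0.09, 2.4, 0.7 and 0.0. The bins of that match are wide for abundant genes, so these percentiles do not show that the lists lay below genes of equal level. For ribosomal proteins, 54 other genes matched more closely, on exon length and level, had a median of -0.72 (interquartile range -1.31 to -0.22). The term ribosome held 69 lower features of 129 against 14.2 by chance (q 3.03e-30), oxidation-reduction process 125 of 409 against 45.1 (q 9.68e-26) and fatty acid metabolic process 26 of 45 against 4.96 (q 2.45e-12). These q values treat genes as independent and take no account of level, so they can overstate the evidence.

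**Figure D3:**
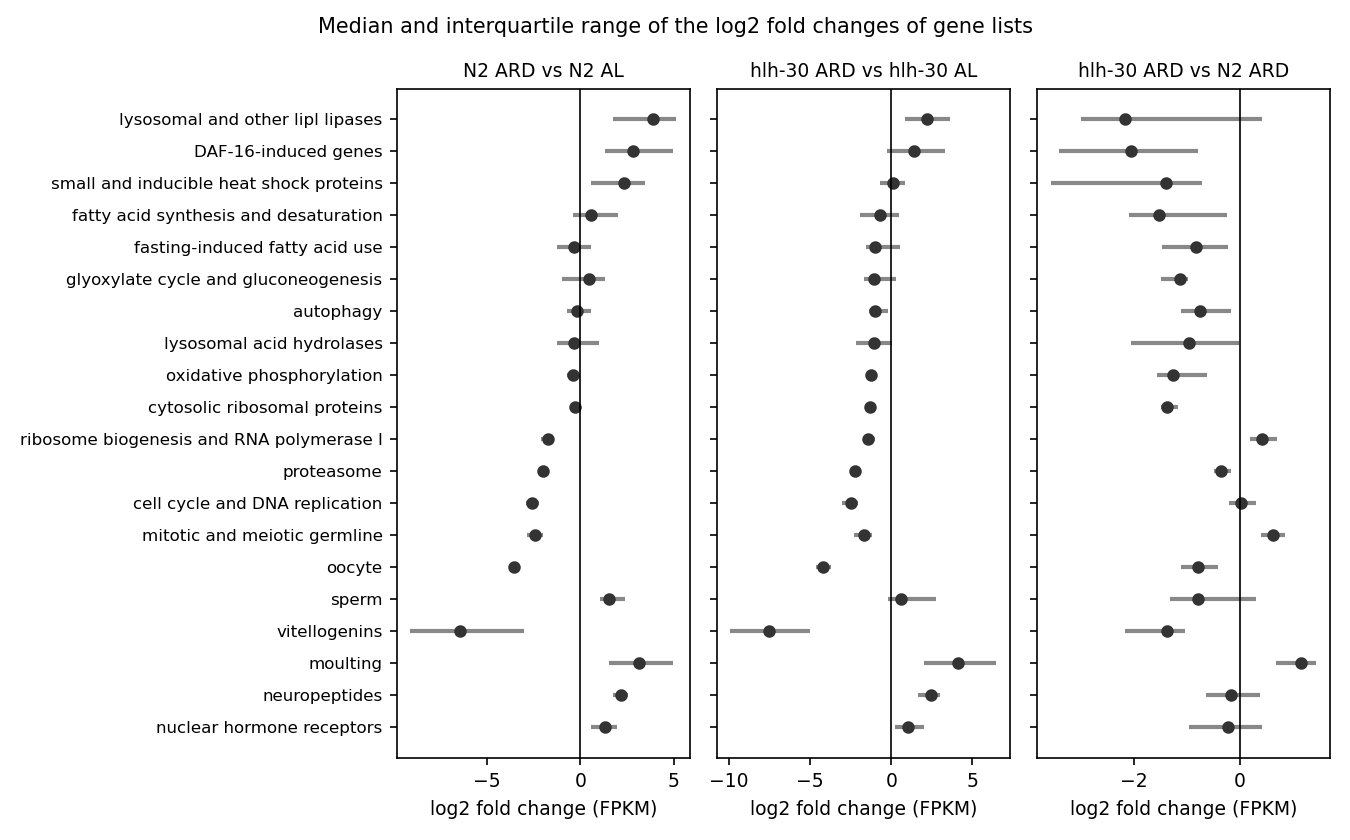
Median and interquartile range of the log2 fold change of 20 gene lists for starvation in N2, starvation in hlh-30, and starved hlh-30 against starved N2, with a different horizontal scale in each panel. The lipase median was 3.92, 2.22 and -2.17, while in the last panel the autophagy median of -0.76 was -0.00 with the equal-sum scaling and the medians of nuclear hormone receptors, neuropeptides and the proteasome turned positive with it.

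On the higher side, moulting had 13 of 25 genes higher and 0 lower (median 1.15) and epidermis 8 of 19 higher and 1 lower (median 1.02; 9 and 1 adjusted over the list alone). The authors' deposited table gave qua-1 2.16, lrp-1 1.96, mlt-11 1.82 (q 0.00390), grd-3 2.45 and nhr-74 4.07. With the equal-sum scaling 20 moulting and 16 epidermis genes were higher. Cuticle collagens went both ways, 23 of 156 higher and 16 lower (16 and 14 adjusted over the list alone), with a median of 0.16 that became -0.01 with the all-feature centring. Germline genes had 9 of 45 higher and 0 lower (5 adjusted over the list alone, median 0.62; 33 with the equal-sum scaling), led by the meiotic msh-5, syp-4 and syp-1 at 1.65, 1.59 and 1.56 in the authors' deposited table, and ribosome biogenesis 3 of 29 higher (2 adjusted over the list alone, median 0.42; 22 with the equal-sum scaling). Sperm genes had 27 of 77 lower and 3 higher (26 and 3 adjusted over the list alone, median -0.79), but with the equal-sum scaling 15 were higher and 3 lower. The major sperm protein gene msp-40, one of many near-identical copies, had -1.90 and the sperm-fate gene fog-3 2.01 in the authors' deposited table. Oocyte genes had 5 of 19 lower (3 adjusted over the list alone, median -0.80), and 1 lower with the equal-sum scaling (median -0.03). Vitellogenins had 3 of 6 lower (median -1.38), and 2 with the equal-sum scaling (median -0.61), vit-5 going from 135 FPKM in N2 to 26.6. Cell cycle genes had 0 of 41 past the threshold, with 4699 of all tested features at an unadjusted p under 0.05, and a median of 0.01 that was -0.16 with the all-feature centring and 0.78, with 12 higher, with the equal-sum scaling.

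Defence genes rose and fell together. The term innate immune response held 62 higher features of 189 against 18.9 by chance (q 2.39e-15). Large rises in the authors' deposited table were those of pme-4, a poly(ADP-ribose) glycohydrolase gene, from 0.555 FPKM in starved N2 to 90.6 in the mutant (7.35), and the cyclic nucleotide channel gene cng-1 (7.16). Some antimicrobial caenacin and neuropeptide-like genes were higher in the authors' deposited table, with cnc-4 at 3.95, cnc-6 at 3.16, nlp-30 at 3.52, nlp-29 at 3.18 and nlp-25 at 2.87, as was the infection response gene irg-2 at 4.17. Other defence genes were lower, with spp-1 at -4.76 (q 0.00993), clec-48 at -4.52 and ilys-3 at -4.02 in the authors' deposited table. The lysozyme and saposin list had 15 of 35 lower and 4 higher (16 and 4 adjusted over the list alone, median -0.80; 10 and 9 with the equal-sum scaling). Of insulin-like genes 6 of 36 were higher and 7 lower (5 and 4 adjusted over the list alone, median -0.21, 0.55 with the equal-sum scaling). The authors' deposited table gave ins-6, daf-28 and the TGF-beta ligand daf-7 2.33, 2.36 and 2.24 and ins-23 -3.68.

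Mutation effects in fed and starved worms correlated with a Pearson r of 0.382 and a Spearman rho of 0.399 over 14334 features, with 64.7% of the same sign. With no filter the Pearson r was lower, as given with the other processing settings. Lower in both were 71 features, where independent lists would share 12.06, and 7 were higher in both against 1.13. Of the fed mutants' lower features 2 were higher in starved mutants, against 9.76 for independent lists. These comparisons too have no library in common.

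Whether starvation acted differently in the strains was tested directly, as the mutant's log2 fold change minus that of N2 over an SE recovered from the deposited statistics. A negative difference means that the change in the mutant lay below that in N2, whatever the size of either, as for fat-7 with -3.86 in N2 and -7.18 in the mutant in the authors' deposited table. Genes with a negative difference included fatty acid desaturases, the lipase gene lipl-3 and a few genes of fatty acid use and of the DAF-16-induced list, and those with a positive one a few antimicrobial genes. Here too a difference of stage or of tissue shares between the strains is not excluded as a source. Of 16164 features 162 passed, 69 with a positive difference and 93 with a negative one, and 1442 had an unadjusted p under 0.05; with the equal-sum scaling 135 of 186 were positive. On simulated data the test found 31 of 50 planted differences of 4 on the log2 scale and 0 of 50 of size 1, so smaller differences are largely outside its reach.

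The responses of fat-5 and fat-6 differed by -5.83 (SE 0.854, q 0.01) and -4.47 (SE 0.493, q 0.00430), and those of fat-7 and dgat-2 by -3.32 and -4.05, 4 of 24 genes of their list and 0 in the other direction (10 and 1 adjusted over the list alone, median -1.24). The response of lipl-3 differed by -5.79 (SE 0.893, q 0.0115), alone among 7 lipases (4 adjusted over the list alone, median -1.77). In fatty acid use hacd-1, acs-2 and acdh-1 differed by -4.37, -3.46 and -3.33 (3 of 34 negative, 6 negative and 1 positive adjusted over the list alone, median -0.70), and icl-1 by -3.94 (SE 0.494, q 0.00743). Among DAF-16-induced genes 5 of 24 differed (7 adjusted over the list alone, median -1.17), with tts-1 at -5.19 (SE 0.513, q 0.00252) and hsp-12.6 at -5.03, and small heat shock proteins had 3 of 12 (4 adjusted over the list alone, median -1.06). The factor genes mdl-1 and mxl-3 differed by -3.39 and -3.31, and the lysosomal cpl-1, asp-8 and asp-13 by -2.50, -2.91 and -2.79 (3 of 35, 7 adjusted over the list alone, median -0.29 that became 0.23 with the equal-sum scaling). The difference was positive for pme-4 by 8.17 (SE 0.797, q 0.00252), cng-1 by 7.02 (SE 0.894, q 0.00743), the antimicrobial cnc-6 and cnc-4 by 5.20 and 4.13, nlp-34 by 3.82 and the P450 gene cyp-14A5 by 4.36. The term innate immune response held 9 features of 185 with a positive difference against 0.753 by chance (q 2.74e-05), and fatty acid metabolic process 6 of 45 with a negative one against 0.272 (q 5.59e-05). Ribosomal protein, oxidative phosphorylation, autophagy, moulting, germline, oocyte and sperm genes had 0 past the threshold, with medians of -0.99, -0.99, -0.62, 1.45, 0.62, -0.71 and -0.81. Differences of this size in single genes are largely outside the reach of the test, so these lists are not shown to respond alike in the strains. Against random lists matched on level, the ribosomal, oxidative phosphorylation, autophagy, oocyte and sperm medians lay at percentiles 0.0, 0.09, 0.0, 1.75 and 0.0, and that of the TCA cycle (0 of 18, median -0.56) at 4.59. The moulting and germline medians lay above those of all 10000 random lists. The equal-sum scaling, with shifts of -0.87 for the mutant and -0.35 for N2, raises the medians of all these lists alike. The negative ones move closer to no difference, and the percentiles stay as they are.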

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

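The test of whether starvation acted differently in the strains was chosen after the data were seen, as were all the tests named here except that of short transcripts. The results singled out are differences between the strains in the log2 response to starvation, mutant minus N2. In all 162 of 16164 features passed that test. A negative value means that the change in the mutant lay below that in N2, not that it was smaller. Negative values were led by those of the desaturase gene fat-5 (-5.83), the lipase gene lipl-3 (-5.79), the lectin gene clec-172 (-5.22), the noncoding RNA tts-1 (-5.19), the chaperone genes hsp-12.6 (-5.03) and hsp-16.41 (-4.79), the metal transporter gene smf-3 (-4.69) and fat-6 (-4.47). Further genes of fat and carbon use were icl-1 (-3.94), acs-2 (-3.46), acdh-1 (-3.33) and fat-7 (-3.32), with the transcription factor gene mxl-3 at -3.31. Positive values were those of pme-4 (8.17), cng-1 (7.02), the antimicrobial cnc-6 (5.20) and cnc-4 (4.13), the receptor gene srg-31 (4.56), irg-2 (3.99), the transporter gene pgp-6 (3.94) and the acyltransferase gene oac-7 (3.92). The genes fat-6 and fat-7, and the hsp-16 genes, have close copies, so reads can be misassigned among them. Outliers among libraries and other splits of the samples could not be examined, because only group values were used.

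Loss of hlh-30 was followed by 122 called features in fed and 3556 in starved worms. Lower precision of the fed comparison does not account for the gap: over 14334 shared features, fed fold changes judged with the starved standard errors gave 68 calls, against 46 with their own and 2471 in starved worms. The deposited scaling of the starved groups does not account for it either, since 2497 calls were left after centring on the median of all tested features. The median absolute log2 fold change was 0.205 in fed and 0.547 in starved worms, at median standard errors of 0.434 and 0.438. For single features the difference of responses was tested, and 162 of 16164 passed. A difference in the need for hlh-30 as the cause of the gap in counts was not tested. It stays open together with a difference of stage or of tissue shares between the starved strains, and with library batches, which group values cannot show.

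Cytosolic ribosomal protein genes were lower in starved mutants than in starved N2, with a median of -1.39 over the 74 of 75 genes that have an exon length. The deposited scaling is excluded as the whole cause, because their median lay -1.55 from that of all tested features with an interquartile range of 0.281. Short transcript bias stays open: 54 other genes of like exon length and level had a median of -0.72 (interquartile range -1.31 to -0.22), more than 50% of the ribosomal value, the bound set in advance. Part of the fall may therefore come from a loss of short or very abundant transcripts in those libraries, and the match is incomplete, with median exon lengths of 510.0 and 614.5 and mean FPKM of 4506 and 2584. A reduced translation program in starved mutants stays open as well and was not tested apart from these. In fed mutants against fed N2 the ribosomal median of -0.39 lay on the same side, with 0 of 75 genes past the threshold.

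Fed libraries labelled mid L3 held abundant transcripts of adults, with a median vitellogenin of 1571 FPKM in fed N2 against 5.92 for the median tested feature, above 99.0% of features. An exchange of the AL and ARD labels is excluded, since 7 of 7 lipl genes, known to rise on fasting, were higher in the libraries labelled ARD. The oocyte list also had a median of 432 FPKM in fed N2. Adult and oocyte transcripts at these levels argue against fed libraries made only of mid L3 larvae. Whether the fed worms were all or in part past the mid L3 when collected stays open. The vitellogenin and oocyte levels are the pattern itself and cannot tell these apart, and stage was known only from the labels. Adult transcripts were not confined to the fed libraries. The authors' deposited table gave vit-2 3538 FPKM in fed and 2123 in starved N2, and the adult collagen col-19, chosen after the values were seen, 2395 and 1863 in N2 and 1711 and 1614 in the mutant. Neither passed between fed and starved N2. If stage did differ between AL and ARD, the falls of yolk, oocyte and germline genes could reflect both starvation and age. The rises of moulting genes (21 of 25, median 3.14), cuticle collagens (85 of 154, median 3.45) and lin-42 (2.86) are exposed in the same way.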

How the results depend on the processing

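The thresholds of q 0.01 and 2-fold and the unfiltered correlations were chosen before the data were examined, and all other tests and scalings here were chosen after seeing the data. No paired analysis was possible because the table gives no values per library. For the same reason another normalization or count tool, another pseudocount, quantile normalization, leaving out each replicate, a fit of only the 8 libraries compared, and camera or fry for lists were not run.

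Counts for starvation stayed within 1.5 times in every setting, from 6729 to 10602 in N2 (9136 as deposited) and from 9330 to 12275 in the mutant (11247). The count for fed strains, 122, was 62 at q 0.01, 23 when adjusted within the comparison, and with standard errors from the statistic 60 unscaled, 56 with either centring and 42 with equal sums. Adjusting within the comparison lowers it by construction, because the other comparisons hold many small p-values. The count for starved strains, 3556, was 2100.0 at q 0.01 and 7383 with equal sums, and otherwise 2575 to 3527. Of the differences between responses, 162, there were 17 at q 0.01, 514 with a normal reference and 0 with the statistic not multiplied by 2 (1442 at an unadjusted p under 0.05 as tested), and otherwise 133 to 186. Simulated data favoured t over the normal reference, since the latter called 77 unchanged features and the former 2. The correlation of the starvation response between strains ranged from 0.875 to 0.911. The correlation of the mutation effect between diets, 0.382, was 0.251 with no filter, over 18059 features.

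Of 627 gene values named by the rule, 523 kept their side of the threshold at q 0.01, 586 with the all-feature centring, 582 with the 5 FPKM centring and 542 with equal sums. For nhr-49, hlh-30 ARD vs hlh-30 AL, the fall of -0.86 reversed to 0.0112 with equal sums. Of 60 medians of lists with at least 50% of tested members called the same way 40, 35 and 28 changed by less than their spread under the same 3 scalings. Except where a construction is named, the cause was not tested. Equal sums moved starved strains by -0.76, and which transcripts carry the difference in sums was not tested. Depth, which is unknown here, limits the calls of rare transcripts.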

Other observations

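Genes in the next sentences were chosen after their values were seen, except cnc-4, cnc-6, nlp-29, nlp-30 and nlp-34. For 12 caenacin and neuropeptide-like antimicrobial genes, values in starved worms, a q or the difference of responses are given, with no test of the family as a set. In the authors' deposited table cnc-2 was at 7.55 FPKM in starved N2 and 114.8 in the starved mutant, cnc-7 at 6.75 and 61.1, cnc-10 at 107 and 275, nlp-29 at 64.1 and 582, and nlp-31 at 101 and 632. The gene cnc-11 went the other way, from 115.1 to 48.9 FPKM, and cnc-3 and cnc-8 did not pass (q 0.0575 and 0.108) in the authors' deposited table. The response to starvation differed between the strains for cnc-2 (3.88, q 0.0369), cnc-4 (4.13, q 0.0116), cnc-6 (5.20, q 0.0345) and nlp-34 (3.82, q 0.0354), and not past the threshold for cnc-7 (q 0.0741), nlp-31 (q 0.0988), nlp-29 (q 0.109) or nlp-30 (q 0.155).

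The adult cuticle collagen gene col-19, also chosen after its values were seen, was abundant in every group, at 2395 FPKM in N2 AL, 1863 in N2 ARD, 1711 in hlh-30 AL and 1614 in hlh-30 ARD in the authors' deposited table, and passed in no comparison used here.

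Within 2 Mb of hlh-30, 8 of 554 tested features, hlh-30 itself among the 8, were called between fed mutant and fed N2, against 122 of 14726 over the whole genome.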
